A study of Danio rerio with 8 samples.

How the data were processed

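Neutrophils were sorted by fluorescence from infected zebrafish larvae that had been raised at 28 °C in medium with 0.003% PTU, an inhibitor of pigment formation, and dissociated in 0.25% trypsin, per the labels' protocols. Complementary DNA was made directly from cell lysates with a SMART-Seq v4 kit and libraries with a Nextera XT kit, per the labels' protocols. The samples were 4 per2-/- and 4 WT replicates, grouped by the genotype in the labels.

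The submitters' processing notes name HISAT2, Cufflinks, Cuffnorm and DESeq, without versions, and the genome build GRCz10. The counting program was not given in the sources used here. The authors' deposited table held 1059 genes, the largest adjusted p being 0.0497, so genes that did not pass were not analysed here. The sample columns hold a signal, gene read counts that the authors divided by 1 size factor per library, as inferred from the values. All values in each library (100.0%) were whole multiples of 1 step within 0.1 read, which gave back the reads. The size factors were 1.11, 0.870, 1.21 and 2.37 in WT and 0.836, 0.587, 0.957 and 1.14 in mutants, so 1 read stood for 0.423 normalised reads in the library labelled WT 4 and for 1.70 in mutant 2. The log2 fold changes, per2 mutant over WT, and their standard errors are the authors' values, per the file headers. The test score in the authors' deposited table equals the log2 fold change divided by its standard error. The p-values and adjusted p-values are the authors' values, and their ratio by rank implies 22876 tested genes. The layout of the columns is that written by DESeq2, per the file headers.

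The log2 fold changes and adjusted p-values in the report are those of the authors' deposited table, with no test of the difference added to them. Means and SDs were computed from the normalised counts of the 4 libraries per group. The level of per2 was tested with an exact permutation test on log2(value + 1). As added alternatives, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 in R 4.3.3 were run on the recovered reads with the authors' size factors, and adjusted by Benjamini-Hochberg over 22876 genes. The spread in both was estimated from genes already selected for a difference, so their p-values may be too small. Only the 1059 listed genes were ranked in that adjustment. For given p-values, the adjusted p-values are therefore upper bounds, and a gene that did not pass may do so with all genes ranked. Tested on simulated data of 1059 genes, edgeR recovered 28% of genes changed 2-fold and 87% of genes changed 4-fold, and 3.36% of its calls were false. That simulation was adjusted over 1059 genes, not 22876, and took its spread from the same selected genes. These rates therefore do not describe the refits on the recovered reads. Other values were computed in Python 3.11.15 with scipy 1.17.1.

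Before the data were examined, 28 gene lists, the alternatives and the rule for named genes were fixed. The rule took per2, the 10 largest increases and 10 largest decreases among genes at or above the median level of the listed genes with established symbols and a value above 0 in both groups, up to 2 genes per list and direction, and 6 genes whatever their values (hmgb1a, cxcl8a, il1b, tnfa, nfkb1, nfkbiaa). It named 50 genes that are reported, and genes named outside it are marked where they appear. Lists with at least 5 listed genes were tested for direction against the other listed genes with Fisher's exact test, which applied to 2 lists. Of the 28 lists 27 are reported, and 1 is not reported here. Enrichment, and counts adjusted over the list alone, could not be computed from genes that had all passed the test.

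Symbols and identifiers were those of the authors' deposited table, in which 110 rows had no identifier, 12 had more than 1 Ensembl identifier and 2 had date-like names. Of 723 rows with an Ensembl identifier, 722 matched the name table used here. Gene positions in GRCz10 were not used here. Neighbouring genes were taken from the assembly GRCz12tu for their order alone, and 788 of 833 genes without a LOC name were placed (94.6%), while 226 LOC genes were left out. Strong changes were shuffled 10000 times among the placed genes. Tested on simulated labels over 788 genes, the neighbour permutation test gave p = 0.698 for shuffled labels and p = 0.0001, the smallest it can give, for planted neighbours.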

Results

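Gene expression was measured by RNA sequencing in neutrophils, the phagocytes that are recruited early to sites of bacterial infection, from zebrafish larvae that were either wild type (WT) or per2-/- mutants. The gene per2 encodes a light-inducible Period protein of the circadian clock. All larvae carried a red fluorescent reporter driven by the neutrophil gene lyz and received 1000 colony-forming units of Salmonella Typhimurium at 52 h post fertilization, 4 h after lights on. At 3 h after infection, 1000 fluorescent neutrophils per sample were sorted, and 4 biological replicates per genotype were sequenced. The comparison asked how loss of per2 changed the neutrophil transcriptome during infection. Uninfected neutrophils were not analysed here. The values cover 1059 genes that passed an adjusted p of 0.05 in the authors' deposited table. Over these genes the recovered reads ranged from 346261 (WT 2) to 445173 (WT 3) in WT and from 645265 (mutant 1) to 1116971 (mutant 3) in mutants. These sums cover part of each library, and the total depth is unknown. Within the WT group, libraries 1 and 3 were closest, with a chi-square per degree of freedom of 3.86 against 21.8 to 52.2 for the other WT pairs. Among mutants, libraries 2 and 3 were closest, at 23.8 against 62.2 to 259 for the other mutant pairs. This chi-square is computed on reads, so abundant genes weigh most in it. The log2 correlation of mutants 2 and 3 was 0.968, little above the 0.943 to 0.953 of the other mutant pairs. No pair of libraries agreed within sampling noise, which does not show that they were independent. Each was counted as a separate replicate.

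The targeted gene was examined in every library before the other genes. In WT, per2 (ENSDARG00000034503) had normalised read counts of 2188, 1733 and 1931 in libraries 1 to 3 and 320 in the library labelled WT 4. The mutant libraries held 252, 279, 329 and 374, so the library labelled WT 4 lay within the mutant range. The group means were 1543 ± 836 in WT and 309 ± 53.9 in mutants (SD, n = 4). In the authors' deposited table per2 fell by 2.32 on the log2 scale, with a standard error of 0.49 and an adjusted p of 0.000349. A two-sided exact permutation test of the mean log2(value + 1) over 70 splits gave a difference of -2.02 and p = 0.0857. Without the library labelled WT 4 the difference was -2.67 with exact p = 0.0286, the smallest p that 3 against 4 libraries allow. The per2 call was lost in edgeR without mutant 2, without mutants 2 and 3, and with the replicate block, at log2 fold changes of -2.28, -2.30 and -2.10. Every direction given for the WT group includes the library labelled WT 4.

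Most genes that changed were higher in per2 mutants. The authors' deposited table listed 747 genes higher (70.5%) and 312 lower, out of 22876 genes implied by its adjusted p-values. Genes listed higher were more abundant, with a median normalised count of 179 against 36.9 for genes listed lower. An absolute log2 fold change of 2 or more was reached in the authors' deposited table by 249 higher and 195 lower genes, and of 3 or more by 64 higher and 93 lower genes. The groups did not overlap in 917 genes (86.6%). Chance alone gives 2.86% of genes with 4 against 4 libraries, but these genes had been selected for their difference. Refitted by edgeR on the recovered reads with Benjamini-Hochberg adjustment, 615 of the 1059 genes passed (428 higher, 187 lower), all with the sign of the authors' deposited table. Leaving out 1 library at a time gave 271 without mutant 2, 337 without WT 1, 353 without mutant 3, 377 without WT 3, and 517 to 546 without each of the others, with 528 without the library labelled WT 4 (351 higher, 177 lower). Without mutants 2 and 3, chosen for removal after their heat shock values were seen, 162 passed (107 higher, 55 lower), with 2 mutant libraries left.

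**Figure D1:**
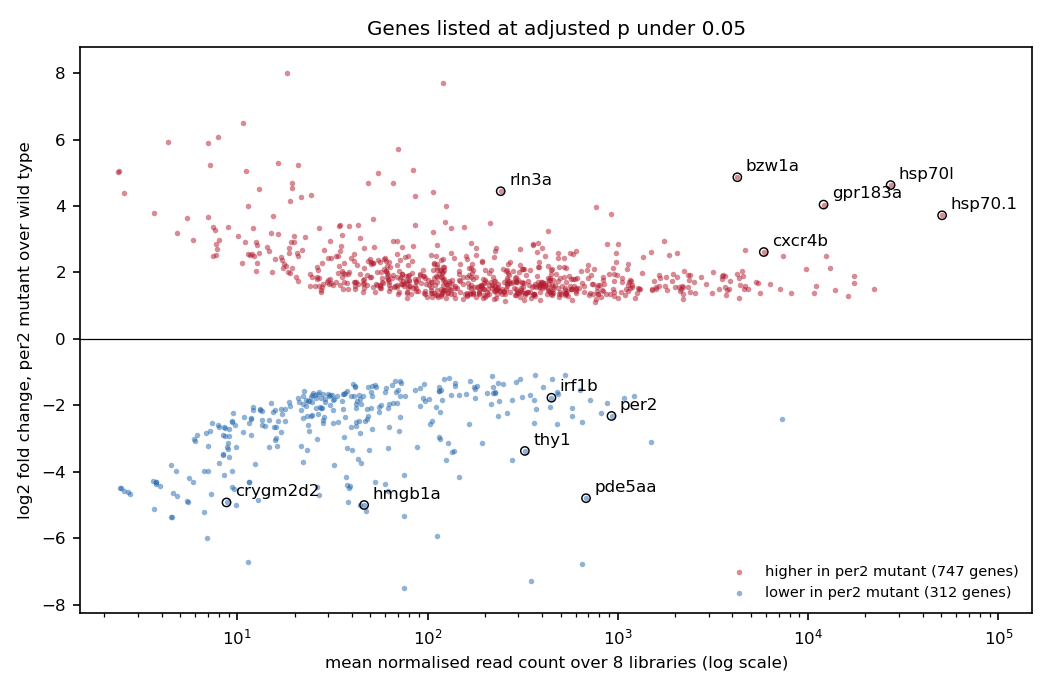
Log2 fold change of per2 mutant over WT from the authors' deposited table (vertical axis) against mean normalised read count over 8 libraries (log horizontal axis), 1 point per listed gene. The 747 genes listed higher are red, the 312 listed lower are blue, and circles mark genes named in the text.

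Among abundant genes with an established symbol, bzw1a, hsp70l, rln3a and gpr183a had the largest increases. The gene bzw1a (ENSDARG00000010481), encoding a regulator of translation initiation, rose from 282 ± 122 normalised reads in WT to 8204 ± 1957 in mutants (SD, n = 4). The oxysterol receptor gene gpr183a (ENSDARG00000010317), which guides immune cell migration, rose from 1380 ± 542 to 22706 ± 6016 (SD, n = 4). In the authors' deposited table, these were log2 fold changes of 4.86 (SE 0.43, adjusted p 4.18e-26) and 4.04 (SE 0.42, adjusted p 4.63e-18). The authors' deposited table gave increases of 4.44 for rln3a, a relaxin-family peptide hormone gene, 3.51 for the dicarboxylate transporter gene slc13a2, 3.49 for lpar5b, a lysophosphatidic acid receptor gene, and 3.36 for atxn10. Its values for pdcd4b and arrb2a, the latter encoding a beta-arrestin, were 3.26 and 2.95 in the authors' deposited table. For lpar5b the adjusted p in the authors' deposited table was 0.0492, its groups overlapped, and mutants 2 and 3 held 493 and 617 of its 1183 mutant reads. Refitted in edgeR, lpar5b passed without mutant 4 (3.91) but not with every library, and its log2 fold change was 4.22 without WT 2, 2.81 without mutant 2 and 0.24 without mutants 2 and 3. Removal of mutants 2 and 3 also lowered rln3a to 3.38, which still passed, and arrb2a (to just above 2) and pdcd4b (to 1.27), which did not, and pdcd4b did not pass without the library labelled WT 4 either (3.11).

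Among decreases, pde5aa (ENSDARG00000056806), encoding a cyclic GMP phosphodiesterase, fell from 1313 ± 523 to 47.4 ± 13.8 normalised reads (SD, n = 4). The chromatin protein gene hmgb1a (ENSDARG00000099175) fell from 90.1 ± 23.7 to 2.68 ± 2.22 (SD, n = 4). Its reads were 134, 76, 109 and 148 in WT and 4, 0, 4 and 2 in mutants, so for hmgb1a the library labelled WT 4 lay with the other WT libraries. The authors' deposited table gave a log2 fold change of -4.80 for pde5aa (SE 0.43, adjusted p 6.10e-25) and a 32.0-fold lower level for hmgb1a (log2 SE 0.64, adjusted p 9.67e-12). Further decreases in the authors' deposited table were -3.63 for the kinase gene stk17b, -3.37 for the surface glycoprotein gene thy1, -3.12 for the sarcomere gene tcap, -2.94 for the matrix gene tnxba and -2.58 for the protein kinase C gene prkchb. It also gave -2.56 for cad, a pyrimidine synthesis gene, -2.51 for rbm38, and -2.33 for both pigrl2.3 and commd6 in the authors' deposited table. The stk17b reads were uneven, at 31, 436, 464 and 41 in WT against 11, 12, 22 and 21 in mutants. Neither stk17b nor tcap passed in edgeR with every library (-3.62 and -3.12), while stk17b passed without WT 1 (-3.99) or the library labelled WT 4 (-4.01) and tcap without WT 1 (-3.46) or WT 3 (-3.49). Their lowest changes with 1 library left out were -2.92 for stk17b without WT 2 and -2.35 for tcap without the library labelled WT 4. For tcap, 1205 of 1578 WT reads came from the library labelled WT 4, and for thy1 that library held 106 of 2608. The thy1 call was lost in edgeR without WT 2 or mutant 3, at -3.31 and -3.36, and without mutants 2 and 3 those of thy1 (-3.52), prkchb (-2.54), cad (-2.36), rbm38 (-2.31), pigrl2.3 (-2.10) and commd6 (-2.30) were lost. Reads of pigrl2.3 are uncertain, since its row carries more than 1 gene identifier and belongs to a multigene family.

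**Figure D2:**
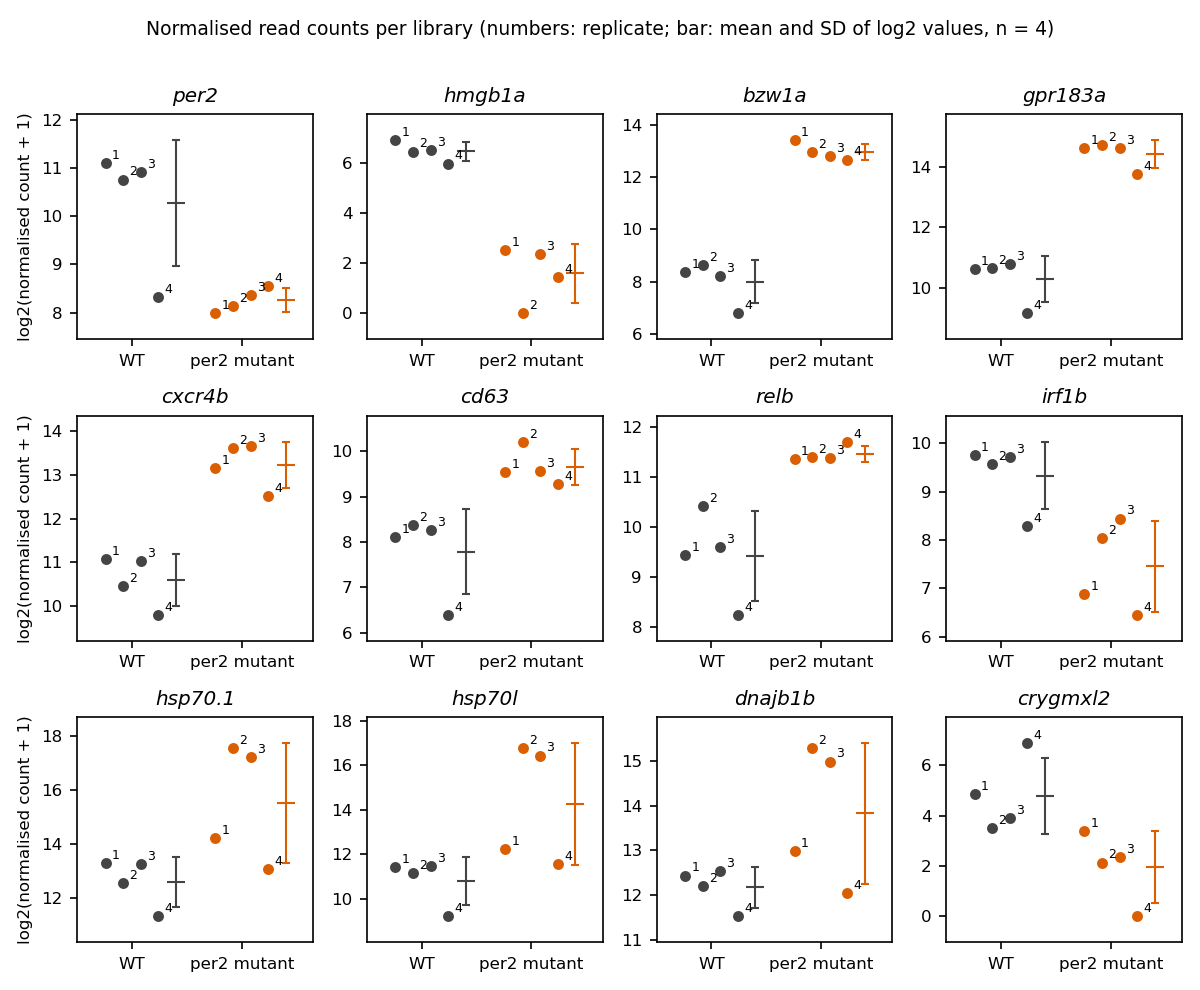
Normalised read counts on a log2(value + 1) scale for 12 genes in each library, with the replicate number beside each point and the mean ± SD of the log2 values (n = 4) beside each group. The library labelled WT 4 lies at the mutant level for per2, and mutants 2 and 3 lie above mutants 1 and 4 for hsp70.1, hsp70l and dnajb1b.

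Listed genes of the neutrophil identity and granule lists were higher in mutants. So were 70.5% of all listed genes and 86.2% of those at or above the median level. Both lists held too few listed genes for the direction test. Of the fixed list of neutrophil identity and migration genes, 4 were listed, and all 4 were higher and at or above that level. These were cxcr4b, whose chemokine receptor retains neutrophils in haematopoietic tissue, cd63, the myeloid transcription factor gene spi1b and the integrin gene itgb2, of which spi1b and itgb2 were named after their values were seen. The level of cxcr4b rose from 1641 ± 602 to 10046 ± 3240, and that of spi1b from 11520 ± 4750 to 32652 ± 7246 (SD, n = 4). In the authors' deposited table the log2 fold changes were 2.61 for cxcr4b (adjusted p 1.11e-07) and 1.73 for cd63 (adjusted p 0.00657). The authors' deposited table also gave 2.83-fold increases for spi1b (adjusted p 0.0138) and itgb2 (adjusted p 0.0266). Of the granule and antimicrobial list, abcb9 (4.26) and scpp8 (1.60) were higher in the authors' deposited table. Outside the lists, the peroxidase gene epx, named after its value was seen, was lower (-1.79, adjusted p 0.0141) in the authors' deposited table. Mutant 2 held 70 of the 114 mutant reads of abcb9, and in edgeR with Benjamini-Hochberg adjustment abcb9 did not pass without that library (2.78) or without the library labelled WT 4 (3.81), while scpp8 passed without the library labelled WT 4 (1.36) but not with every library (1.60). All 6 listed genes of the 2 lists were lower in the library labelled WT 4 than the mean of the other WT libraries, by a median log2 ratio of -1.46. Over all 747 genes listed higher that median was -0.83. The gene abcb9 had only 3, 0, 6 and 2 WT reads and was lowest in WT 2. In edgeR with Benjamini-Hochberg adjustment 2 of the 4 identity genes passed with every library (not spi1b and itgb2), and 4 passed without the library labelled WT 4. The cd63 call was also lost without mutant 2 and without WT 1, WT 3 or mutant 3 (1.77 to 1.84 for these), and with only 2 mutant libraries left, without mutants 2 and 3, none passed, at smaller log2 fold changes of 2.19 for cxcr4b, 1.45 for cd63, 1.22 for spi1b and 1.24 for itgb2.

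Few genes of the fixed inflammatory lists were listed. Of the cytokine and chemokine list, il22 and lta were higher, with log2 fold changes of 2.28 (adjusted p 0.00665) and 1.86 (adjusted p 0.0198) in the authors' deposited table. The NF-kB subunit gene relb rose from 780 ± 438 to 2820 ± 340 normalised reads (SD, n = 4), a log2 fold change of 1.86 in the authors' deposited table. The intracellular bacterial sensor gene nod1, from the Toll-like receptor and inflammasome list, rose from 44.8 ± 4.86 to 188 ± 93.4 (SD, n = 4). Of the interferon list, the transcription factor gene irf1b and the antiviral gene mxe fell, with log2 fold changes of -1.77 (adjusted p 0.0127) and -1.73 (adjusted p 0.0352) in the authors' deposited table. From the complement and acute phase list, saa (4.43-fold) and cfi (2.83-fold) were higher in the authors' deposited table. Refits in edgeR did not call lta, mxe and cfi with every library, while without mutant 1 lta (2.15) and mxe (-2.47) passed, and nod1 and saa passed in every refit. The il22 call was lost without WT 1, WT 3, the library labelled WT 4, mutant 2 or mutant 4, at log2 fold changes of 1.69 to 2.26, and leaving out 1 library ended the calls of relb in 5 of 8 refits (1.77 to 1.88) and of irf1b in 6 (-1.91 to -1.52), although irf1b passed without mutants 2 and 3 (-2.76). The genes cxcl8a, il1b, tnfa, nfkb1 and nfkbiaa were not among the 1059 listed genes. The fixed lists do not hold every immune gene. Outside them, unc93b1 (-1.59) and irf10 (-1.86) were lower in the authors' deposited table, and tyk2 (1.45) and ccr12b.2 (2.03) higher. These were named after their values were seen, and further immune genes outside the lists were not counted.

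Of the heat shock and unfolded protein list, 8 genes were listed, 7 higher and 1 lower. The chaperone gene hsp70.1 rose from 7134 ± 3562 to 93950.2 ± 94151 normalised reads and hsp70l from 2108 ± 1045 to 52108 ± 56427 (SD, n = 4). The mutant values of hsp70.1 were 19058, 195025, 153058 and 8660, and those of hsp70l were 4858, 111803, 88773 and 3001, so both increases came mainly from mutants 2 and 3. In the authors' deposited table the log2 fold changes were 3.72 for hsp70.1 (SE 0.98, adjusted p 0.00697), 4.63 for hsp70l (SE 1.13, adjusted p 0.00275) and 2.73 for hspb1 (SE 0.64, adjusted p 0.00174). The other higher members, named after their values were seen, were dnajb1b (2.15), dnajb1a (1.94), dnaja1 (1.75) and calr (1.51) in the authors' deposited table, and the transcription factor gene hsf2 was lower at -1.73. The split of 7 to 1 did not differ from that of the other listed genes (two-sided Fisher's exact test, p = 0.449, Benjamini-Hochberg adjusted 0.449). In edgeR with Benjamini-Hochberg adjustment only hsp70l and hsp70.1 of the 8 listed genes passed with every library. Without the library labelled WT 4 neither passed, with log2 fold changes of 4.32 and 3.44, while hsf2 did. None of the 8 passed without mutant 2, where the log2 fold changes were 3.93 for hsp70l and 3.08 for hsp70.1. Leaving out 1 library ended the hsp70l call in 6 of 8 refits and the hsp70.1 call in 3, and without mutants 2 and 3 none of the 8 genes passed and the log2 fold changes fell to 0.90 for hsp70l and 0.96 for hsp70.1.

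Clock and metabolic lists held few listed genes. Besides per2, the clock output gene tefa and the repressor gene bhlhe41 were listed, higher by 1.43 and 2.13 in the authors' deposited table. The fixed list does not hold every clock-linked gene. Outside it, cipcb (2.2), klf9 (2.55) and usp2a (1.45), named after their values were seen, were also higher in the authors' deposited table. Without the library labelled WT 4, cipcb passed in edgeR, while klf9 and usp2a did not. The bhlhe41 values were low, at 6.64 ± 4.17 in WT and 28.0 ± 12.0 in mutants (SD, n = 4). Of the glycolysis list, the pyruvate dehydrogenase kinase gene pdk2b (2.60) and the lactate dehydrogenase gene ldhba (2.50) were higher in the authors' deposited table. The nuclear-encoded oxidative phosphorylation gene cox5b2 (2.26) and the autophagy genes atg4b (1.35) and map1lc3a (1.26) were also higher in the authors' deposited table. The ribosomal protein gene rpl39 was lower, at -4.43 in the authors' deposited table, with 254 of 416 WT reads in WT 1 and 158 in the library labelled WT 4. Of the immediate early list, klf2a was higher (2.58) and egr4 lower (-2.08) in the authors' deposited table. In edgeR with Benjamini-Hochberg adjustment tefa, bhlhe41, atg4b and map1lc3a passed neither with every library nor with any 1 left out, at log2 fold changes of 0.97 to 2.35. With the replicate block added, tefa and atg4b passed. The genes rpl39 (-2.79 without WT 1) and egr4 did not pass with every library but did without WT 3 (rpl39, -4.80) and without the library labelled WT 4 or mutant 4 (egr4, -2.43 and -2.50). For klf2a, 35 of 43 WT reads came from the library labelled WT 4, without which its log2 fold change was 3.79 and passed, and its call was lost in 6 of the other 7 refits with 1 library left out (log2 fold changes above 2). The call of cox5b2 was lost without WT 1, the library labelled WT 4 or mutant 2 (1.92 to 2.16), and that of ldhba without WT 1 or mutant 2 (2.44 and 2.36), and pdk2b passed in every refit. No gene was listed from the light-induced DNA repair, mitochondrially encoded or cell cycle lists. Genes of these kinds outside the fixed lists were not counted.

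Markers of other cell types were examined because the cells were sorted from whole larvae. Of the lens and retina list, 5 genes were listed and all 5 were lower in mutants, a split that differed from the other listed genes (two-sided Fisher's exact test, p = 0.00217, Benjamini-Hochberg adjusted 0.00434). Against an even split the adjusted p was 0.0703 (exact binomial test). Both tests treat the genes as independent, yet the crystallins on the list rose together in the library labelled WT 4. Their log2 ratios to the other WT libraries were 2.37 to 3.14 there, so neither p can be read as a difference between genotypes alone. Of crystallin genes outside the list, named after their values were seen, crygn1 was higher (2.08) and crygm2d16 lower (-4.52) in the authors' deposited table. The crystallin gene crygmxl2 fell from 42.1 ± 49.97 to 4.29 ± 3.96 normalised reads (SD, n = 4), and 275 of its 332 WT reads came from the library labelled WT 4. For crygm2d2, 116 of 138 WT reads came from that library and 2 reads were found in mutants. The remaining members, named after their values were seen, were crybb1l1 (-2.41), cryba2b (-2.63) and gnat2 (-1.57) in the authors' deposited table. In edgeR with Benjamini-Hochberg adjustment 2 of the 5, crygmxl2 and crygm2d2, passed with every library. None passed without the library labelled WT 4, where their log2 fold changes were -2.04 and -3.28, or without mutants 2 and 3, where they were -3.26 and -4.01. The erythroid-list gene nt5c2l1 was lower (-2.54) and the connective tissue and endothelium gene fli1a higher (1.42) in the authors' deposited table, and fli1a did not pass in edgeR. For nt5c2l1, 199 of 318 WT reads came from the library labelled WT 4, and its edgeR call was lost without that library (-2.10), without mutant 2 (-2.38) and without mutants 2 and 3 (-2.31). No gene was listed from the macrophage, thrombocyte and lymphoid, muscle, epidermis, neural, or yolk, liver and pancreas lists. These lists are not complete: the sarcomere gene tcap, listed lower at -3.12 in the authors' deposited table, is not on the muscle list. Nor are the muscle genes vmhc (-1.73), cacna1sb (-1.72), myot (-1.71) and mybpc2b (-1.22), all lower in the authors' deposited table. Off the lens and retina list, gja8a (-2.6), rs1a (-2.47) and impg2a (-1.87) were also lower in the authors' deposited table. Apart from tcap, these genes were named after their values were seen. Genes of these tissues outside the lists were not counted in either direction. Absence from a list therefore does not show that the genes of a tissue were unchanged.

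**Figure D3:**
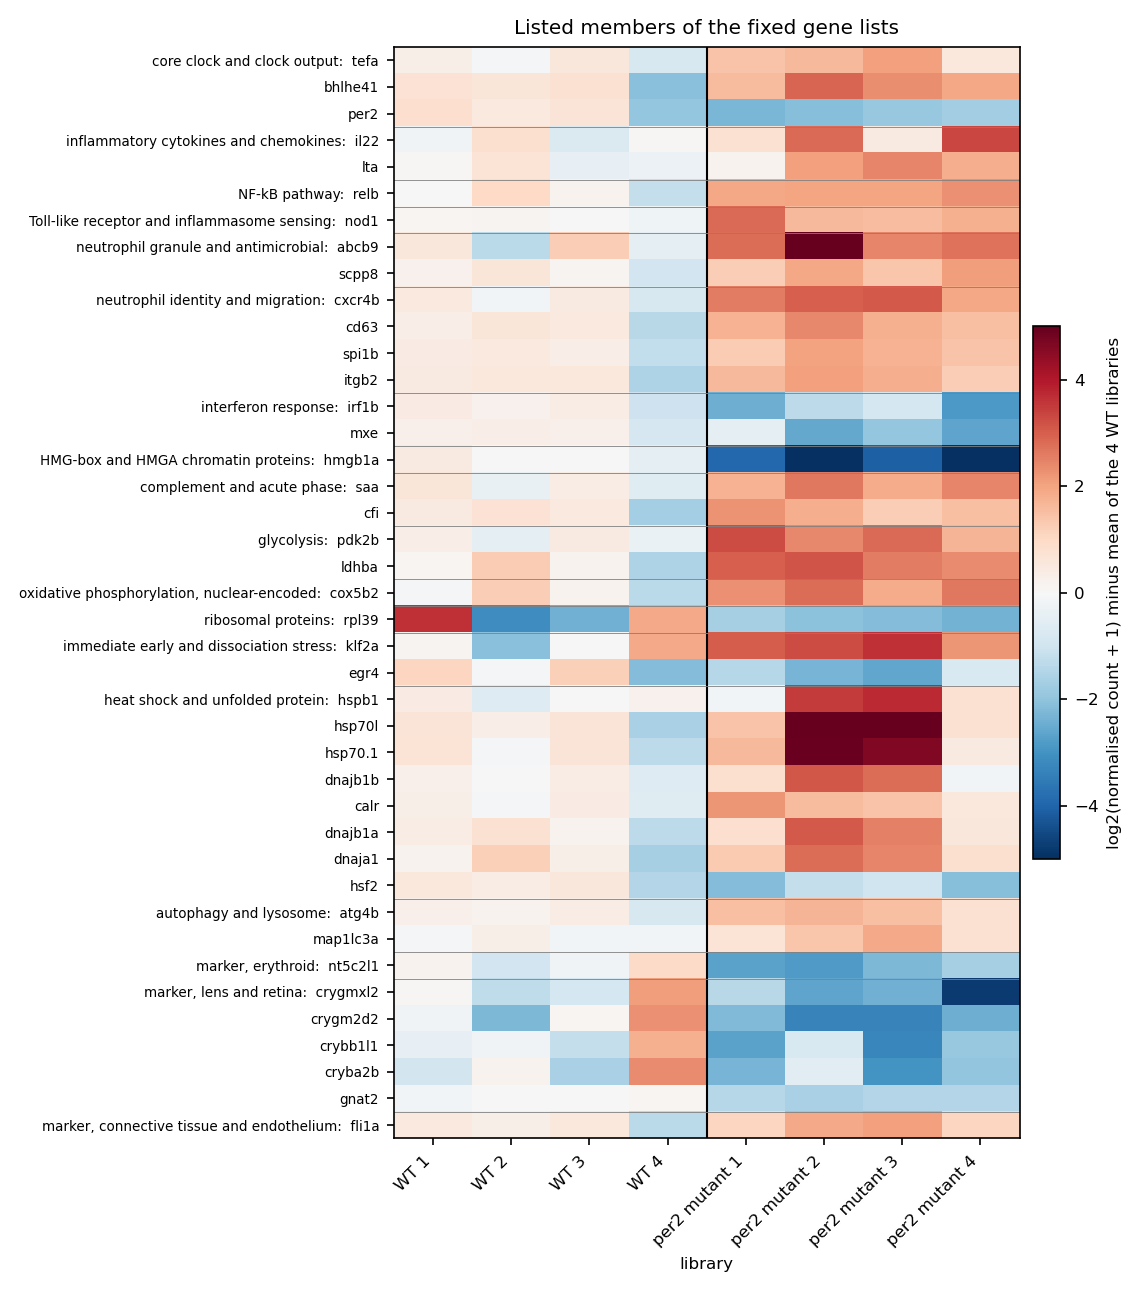
Log2(normalised count + 1) of each listed member of the fixed gene lists in each of the 8 libraries, relative to the mean of the 4 WT libraries, with red above and blue below that mean. Crystallin genes such as crygmxl2 were highest in the library labelled WT 4, and heat shock genes such as hsp70.1 were highest in mutants 2 and 3.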

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

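The tests of a wrong label, of size factors, of the share of higher calls and of heat shock in this part were chosen after the results were seen, and the test for RNA of other cell types was written before the markers' values per library were seen but after spi1b and other neutrophil genes had been seen low in the library labelled WT 4.

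Single libraries stood apart from the other 3 of their group in 11 of 100 groups of values tested (Dixon's ratio on normalised counts). Chance would give about 5.0 if the values were normal and independent. Untransformed counts need not be normal and the genes share libraries, so 11 and 5.0 cannot be compared strictly. The library labelled WT 4 accounted for 5 of the 11. It held 576 normalised reads of gpr183a, 169 of commd6, 0.423 of bhlhe41 and 41.4 of mxe, each below the other WT libraries, and 116 of crygmxl2, above them. WT 2 held 77.05 normalised reads of lpar5b and 353 of map1lc3a, both above the other WT libraries. Among mutants, replicate 4 held 13780.0 of gpr183a, below the others, and 3327 of relb, above them. Mutant 1 held 328 normalised reads of nod1 and mutant 2 held 119 of abcb9, each above the other mutants.

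The library labelled WT 4 had per2 at the mutant level, the lowest WT value at 487 of the 747 genes listed higher (65.2%, median log2 ratio to the other WT libraries -0.83) and at 170 of the 312 listed lower (54.5%, median -0.51), and low neutrophil genes. The tables argue against a mutant library under a WT label: among 157 genes with an absolute log2 fold change of 3 or more it lay nearer to the other WT libraries in 136 (86.6%), against 4 to 18 genes in which single mutant libraries lay nearer to WT 1 to 3 than to the other mutants, and in 78 of these genes it lay at least 4-fold beyond the whole mutant range on the WT side, as for hmgb1a with 148 reads against 0 to 4. The comparison with the mutant libraries and the 4-fold count were added after a bound of 90%, itself set after the values were seen, had not been reached, and on 131 genes called without it the share was 75.6%, with all genes selected under the given labels. Within groups the median level of the genes listed higher fell with log2 size factor (r = -0.89, exact permutation p = 0.0139), also without the library labelled WT 4 (r = -0.75). The share of edgeR calls that were higher without that library was 66.5%, and the log2 difference predicted from size factors within groups was 0.37 against a median of 1.75. These values decide neither whether that library nor whether size factors caused the excess of higher genes, since every gene had passed the authors' test. RNA of other cell types and a mixture of cells stay open as candidate sources: 7 listed markers had a median log2 ratio of 2.37 to the other WT libraries, with crygm2d2 at 3.07 and cryba2b at 3.14 but gnat2 at 0.14 and fli1a at -1.77, yet genes enter the table partly through this library, and no biological explanation within the WT group was tested.

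Heat shock genes were high in mutants 2 and 3. The median log2 ratio of the highest to the lowest mutant library over the 7 higher genes was 3.24, against a median of 0.96 in 10000 random sets of other higher genes matched on expression. The random sets draw genes singly, while heat shock genes moved together, so that comparison is descriptive. A spread of this size argues against per2 genotype alone, since the 4 mutant libraries share it. Size factor does not order these libraries, since mutant 1, at 0.84, lay between them. Handling or stress of these samples, alone or together with genotype, may account for it and stays untested, with mutants 2 and 3 both more than 2-fold above mutants 1 and 4 in 52 genes listed higher, against 3 to 6 for the other pairings of mutants.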

How the results depend on the processing

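The refits by edgeR and DESeq2 and the removal of mutants 2 and 3 together were chosen after seeing the data. All refits ran on genes already selected with the given labels, so they can mostly lose calls. Of 1059 genes (747 higher, 312 lower), 527 passed an adjusted p of 0.01 (396, 131), 530 lay at or above the median level (457, 73), and 623 had no clone or locus name (472, 151). In edgeR with Benjamini-Hochberg adjustment 615 passed (428, 187), and 162 passed without mutants 2 and 3 (107, 55). Leaving out 1 library at a time, also in edgeR and so to be set against 615, gave 271 to 546 genes, 178 to 420 higher and 93 to 177 lower. The lowest count was that without mutant 2, and counts without WT 1, WT 3 and mutant 3 were 337, 377 and 353. These libraries form the closest pair within each group, by chi-square per degree of freedom. The cause of these losses was not tested beyond the smaller number of samples. DESeq2 called 1022 (729, 293). The share of higher calls rose from 70.5% to 86.2% among genes at or above the median level. With the replicate block 631 passed (483, 148). Deviations of same-numbered libraries correlated across genes at -0.01, 0.09, 0.09 and 0.09, against -0.09 to 0.02 for differently numbered libraries. All these correlations are weak and the labels name no pairing, so whether the numbers pair the samples is not settled. In every refit with 1 library left out all 1059 genes kept the sign of the authors' deposited table, and without mutants 2 and 3 together 1 changed sign. Of the 50 named genes, 34 passed in edgeR, 33 with the block, 20 to 35 with 1 library left out, 13 without mutants 2 and 3, and 49 in DESeq2. The per2 difference ranged from -1.74 to -2.67 with 1 library left out, and its exact permutation p fell from 0.0857 to 0.0286 without the library labelled WT 4, while a sign-flip test over the 4 numbered pairs gave an exact p of 0.25. Against an even split, the direction of the lens and retina list, with 0.0% higher, gave an exact binomial adjusted p of 0.0703 in place of 0.00434. Other scalings, low-count filters and tests of whole gene sets were not run, because they need the genes that did not pass. Total depth is unknown, and 79 genes had a mean below 10 normalised reads.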

Other observations

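All tests of neighbouring genes in this part, and the count of splits, were chosen after the results were seen.

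Several genes outside the fixed lists, chosen here after their values were seen, differed strongly. The progenitor transcription factor gene myb rose from 7.59 ± 2.75 to 78.4 ± 17.9 normalised reads and hoxb8a from 8.04 ± 4.45 to 95.6 ± 42.3 (SD, n = 4). The receptor gene gpr34a rose from 9.68 ± 5.14 to 203 ± 107 (SD, n = 4). The lipid synthesis genes dgat1a and mogat3a were higher by 2.53 and 2.23 on the log2 scale in the authors' deposited table. The interleukin receptor gene il13ra1 rose from 106 ± 29.9 to 422 ± 84.7 (SD, n = 4).

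Among decreases chosen in the same way, the class I histocompatibility genes mhc1zca and mhc1zda had log2 fold changes of -2.79 and -1.62 in the authors' deposited table. The receptor gene cd180 fell from 120.2 ± 63.2 to 23.6 ± 10.4 normalised reads (SD, n = 4). The genes rca2.2, pigrl2.4 and btr20 had log2 fold changes of -5.93, -5.32 and -5.18 in the authors' deposited table. Read assignment is uncertain for them, since multigene families and possible allelic variants may affect it, which was not tested.

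Strongly changed genes, with an absolute log2 fold change of 3 or more, often lay near one another in gene order. Of 80 such genes, 33 had a strongly changed neighbour without a shared name stem within 50 genes, against 22.9 ± 5.1 (SD) with changes shuffled, permutation p = 0.0329. In this window the excess stayed without paralog-like names, which argues against reads shared between like-named paralogs as its whole source. Paralogs under unlike names and the LOC genes left out were not covered, so shared reads in general stay open. The 4 versions run disagreed: with all pairs 37 genes gave a permutation p = 0.0066, within 20 genes 23 gave p = 0.0054, and within 100 genes 40 gave p = 0.271, none adjusted for the number of versions. Chromosome segments that differ between the 2 fish lines are a candidate explanation, on no genotype or variant data, and shared regulation stays equally open, since 13 of 23 pairs moved in the same direction against 11.4 ± 2.4 (SD) by shuffling (permutation p = 0.297). For a segment around per2 itself, 1 of 12 listed genes within 100 genes was strongly changed against 79 of 775 elsewhere (two-sided Fisher's exact test, p = 1), and 12 genes with LOC genes left out are too few to decide.

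Of the 35 splits of the 8 libraries, 1, the real one, called as many of the listed genes in edgeR with Benjamini-Hochberg adjustment (615), and the highest other split called 2. The genes had been selected on the real split, so this count does not show whether chance can be excluded.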
